A study of Mus musculus with 6 samples.

How the data were processed

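Total RNA from mouse hippocampus at 6 months of age was sequenced in 6 libraries, 3 labelled WT and 3 labelled APP/PS1, and each library came with a gene table and a circRNA table. Per the labels' protocols, tissue was frozen, RNA was taken up in Trizol and libraries were built with an Illumina TruSeq kit. The gene values were read as FPKM deposited by the authors. No header names the unit, and it was taken from the decimals, from totals far below 1000000 and from StringTie, which the submitters' processing notes list with FastQC, HISAT2 and the build mm9, with no versions and no role. The circRNA values deposited by the authors were whole-number read counts with a different total in each library, and the circRNA caller is not given in the sources used here. The labels give no batch, date, litter, sex or pairing and do not say that replicates are separate animals, so p-values measure only the spread between these libraries, which may be technical.

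The gene table held 15639 rows with 15616 distinct names, 21 names standing on more than 1 row. The spreadsheet had turned 22 gene names into dates, and these were not named. Of the distinct names, 15275 were found in the reference name tables. The lowest per-gene maximum was 0.529 FPKM, so the table had been limited to genes reaching about that level in some library. Ratios of low values between a pair of libraries showed no steps that would return whole reads, so the depth behind FPKM stayed unknown and no count test was run on genes. Of 2246 circRNAs, 1989 had only a database number, which the tables used here do not pair with a gene, and 257 had coordinates. Coordinates are printed as the files give them. Although mm9 is listed, 254 of the 257 (98.8%) lay inside at least 1 gene of the GRCm38 RefSeq table. After a shift either way the shares were 89.5% and 85.2% for 10000 bases, and 30.4% and 31.5% for 1000000 bases. Host genes were taken from that table without regard to strand, a single protein-coding gene being preferred over overlapping long non-coding genes. Whether a circle starts or ends in an exon was not analysed here.

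Replicates were compared before averaging. A chi-square per degree of freedom on circRNA counts ran from 2.06 to 2.30 over the pairs within a label and from 2.03 to 2.39 over the pairs across labels, so no library repeated another by this test. Genes with at least 1 FPKM in at least 3 libraries (13700) were tested with limma 3.58.1 (empirical Bayes with trend and robust settings, R 4.3.3) on log2(FPKM + 1), with the label as the only term. Fold changes of genes are on that scale and understate the change of low genes. circRNAs with at least 2 reads in at least 3 libraries (2132) were tested with edgeR 4.0.16 by its robust quasi-likelihood test with TMM factors over circRNAs. Benjamini-Hochberg adjustment was applied over all genes or circRNAs tested, with a threshold of 0.05. Of 34 gene lists, 32 with at least 5 tested genes were tested with camera at a preset correlation of 0.01 and adjusted over the lists, and the sex-linked and transgene lists served as checks of the samples. Counts for a list were also adjusted over the list alone. Single values per library were compared with an exact two-sided permutation test, whose smallest p is 0.1 for 3 against 3. Correlations across genes used 100000 permutations. Exact binomial intervals at 95% are given for shares of single libraries, and a floor of 3 counts stands for a group at 0.

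Lists, tests, alternatives and the rule for names were written before the data were examined. The rule names App and Prnp, the genes past the threshold whose libraries do not overlap between labels (up to 12 per direction, filled up to 8 by smallest p), up to 4 members of each list by smallest p, up to 8 circRNAs per direction filled up to 5, and up to 6 circRNAs of hosts fixed beforehand with an unadjusted p under 0.05. circRNAs known by number alone were limited in the text, and genes without a symbol or with a predicted-gene name were left out. Not all genes that the rule allows are printed, and 1 gene of the rule is not reported here.

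Alternatives were other filters, a pseudocount of 0.1, quantile or TMM scaling of FPKM, limma without trend or with array weights, DESeq2 1.42.0 for circRNAs, other thresholds, the replicate number as a block, an estimated correlation, fry, and each library left out in turn. Chosen after seeing the data were the fit to 4 libraries, without the 2 whose App and Prnp went against their labels, the list of mitochondrially encoded genes and the sums over Nme7 circles. On simulated data made from the means and the spread of these libraries, limma recovered 67% of 1.5-fold and 89% of 2-fold changes among 13700 genes with 11 false calls, and edgeR recovered 2% of 2-fold and 28% of 4-fold changes among 2132 circRNAs with 0 false calls. Folds of genes were set on the log2(FPKM + 1) scale, so low genes changed by more in FPKM. The simulated genes and circRNAs were independent of each other, so these rates need not hold where real ones vary together.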

Results

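Circular RNA and messenger RNA were measured in the hippocampus of mice at 6 months of age. The series held 3 libraries labelled wild type (WT) and 3 labelled APP/PS1, a transgenic model that carries a mutant amyloid precursor protein. The gene table listed FPKM for 15639 rows, of which 13700 genes were tested. The circRNA table listed whole-number reads for 2246 circular RNAs, of which 2132 were tested. Total circRNA reads were 13998, 17843 and 18866 in the libraries labelled WT replicates 1 to 3, and 19584, 18064 and 19448 in the libraries labelled APP/PS1 replicates 1 to 3. FPKM summed to between 182355 and 185217 per library, and the sequencing depth behind the gene values is unknown. A floor of 3 reads corresponded to between 153.2 and 214.3 CPM of circRNA reads, and intervals and floors given here cover counting error only. Means are given with the SD over n = 3 libraries per label unless a single library is named.

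The transgene came first, as a check of the labels. App, the amyloid precursor protein gene, was listed at 69.8 and 68.5 FPKM in the libraries labelled WT replicates 1 and 2, but at 145.6 FPKM in the library labelled WT replicate 3. In the libraries labelled APP/PS1 replicates 1 and 3 it stood at 153.1 and 166.2 FPKM, and in the library labelled APP/PS1 replicate 2 at 71.0 FPKM. Prnp, the prion protein gene, split the libraries in the same way: 188.1, 181.5 and 457.2 FPKM in the WT-labelled libraries against 471.6, 198.6 and 463.8 FPKM in the APP/PS1-labelled libraries. Its promoter was taken beforehand to drive the transgene, though the labels do not name the mouse line. The exact two-sided permutation test across labels gave p = 0.2 for App and p = 0.2 for Prnp, where 3 against 3 libraries cannot go below 0.1. Both App and Prnp thus went against the label of 1 library of each genotype. The groups below are named by label alone, and counts of genes past the threshold over a list alone that then differ are also given without the library labelled WT replicate 3 and the library labelled APP/PS1 replicate 2. In that comparison of 4 libraries, chosen after the values were seen, App had a log2 fold change of 1.19 (limma, adjusted p = 0.0114) and Prnp of 1.34 (adjusted p = 0.00378). The libraries were chosen by these 2 genes, so their adjusted p-values there carry no evidence. Y-linked genes were listed in every library, Ddx3y between 14.7 and 20.4 FPKM and Uty between 5.80 and 6.98 FPKM.

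**Figure D1:**
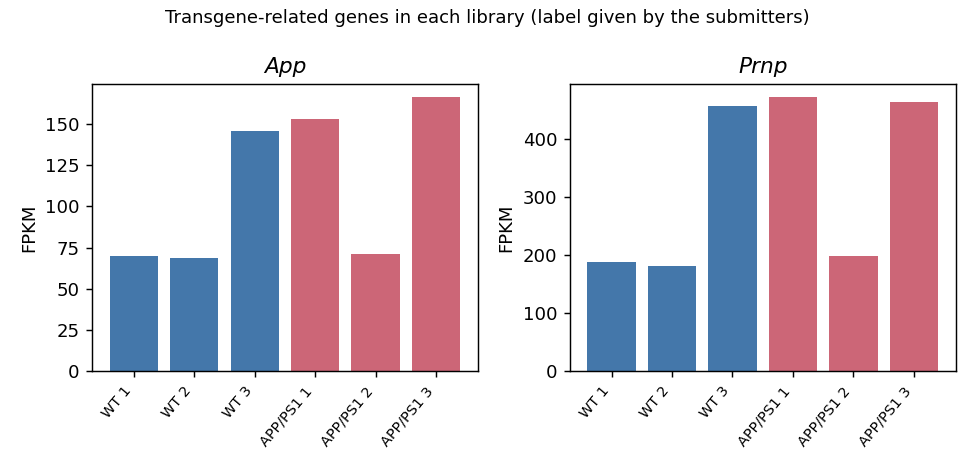
FPKM of App and Prnp in each of the 6 libraries, 1 bar per library, blue for libraries labelled WT and red for libraries labelled APP/PS1. App in the library labelled WT replicate 3 stood at 145.6 FPKM and in the library labelled APP/PS1 replicate 2 at 71.0 FPKM.

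Genes were then compared between labels to ask which messenger RNAs differ in this hippocampus. Tmem127, a membrane protein gene known as a tumour suppressor that restrains mTOR signalling, rose from 3.34 ± 0.358 FPKM in the WT-labelled libraries to 21.6 ± 0.485 FPKM in the APP/PS1-labelled libraries, a log2 fold change of 2.39 (adjusted p = 4.58e-05, higher in 3 of 3 libraries). Cdc42se1, a small effector of the GTPase Cdc42, fell from 14.7 ± 0.189 to 6.10 ± 0.489 FPKM (log2 fold change -1.14, adjusted p = 0.00212). Tspan5, a tetraspanin known to bind the alpha-secretase ADAM10, fell from 18.2 ± 0.923 to 7.48 ± 0.854 FPKM (log2 fold change -1.18, adjusted p = 0.00709). These 3 were the genes past an adjusted p of 0.05 by limma, 1 higher and 2 lower, while 916 genes had an unadjusted p under 0.05 where 685 were expected by chance, 391 of them higher and 525 lower. Other splits of the 6 libraries into 3 against 3, made after the values were seen, gave between 399 and 1234 such genes. The count by label thus lay within the range of other groupings, exceeded only by the highest of them. The next lower count, 839, was in the split that App and Prnp follow. Genes next in line did not pass and are given as values. Nme7, a member of the nucleoside diphosphate kinase family, had 3.0 ± 0.364 against 8.38 ± 1.61 FPKM (log2 fold change 1.22, adjusted p = 0.0723). Chpt1, a cholinephosphotransferase of phosphatidylcholine synthesis, had 2.56 ± 0.0647 against 4.59 ± 0.358 FPKM (log2 fold change 0.65), and Socs6, of the suppressor of cytokine signalling family, had 1.52 ± 0.115 against 2.82 ± 0.0872 FPKM (log2 fold change 0.60). Tmem161a, Pde1a, Gucy1a3 and Tmem88b had log2 fold changes of 0.53, 0.38, 0.38 and 0.36. On the lower side, Adarb1, which encodes the RNA-editing enzyme ADAR2, had 14.9 ± 1.04 against 9.41 ± 0.318 FPKM (log2 fold change -0.61, adjusted p = 0.0723). Zfp579 stood at -0.78, Dusp4, a MAP kinase phosphatase, at -0.56, the chaperone gene Dnajb5 at -0.52, Msl1 at -0.39 and Homer1, a postsynaptic scaffold, at -0.37. In the 4 libraries without the 2 that went against their labels, 11 genes were higher and 16 lower by limma, and all 3 genes named first were among them. Leaving out single libraries moved the count of higher genes from 1 to 4 without the library labelled WT replicate 1, 5 without WT replicate 3, 8 without APP/PS1 replicate 2 and 2 without APP/PS1 replicate 3, and the count of lower genes from 2 to 1, 6, 5 and 22 without the libraries labelled WT replicate 2, WT replicate 3, APP/PS1 replicate 1 and APP/PS1 replicate 2, with Tspan5 no longer past the threshold without WT replicate 2 (adjusted p = 0.0863, range over alternatives 0.00519 to 0.151).

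Immediate early genes, transcribed within minutes of neuronal activity, passed on the lower side as a group in the APP/PS1-labelled libraries by camera with a preset correlation (adjusted p = 1.03e-22, and adjusted p = 0.541 with an estimated correlation). All 22 had a negative log2 fold change, with a median of -0.72, and 17 passed when adjusted over the list alone, though 0 passed over all genes tested (18 had an unadjusted p under 0.05). Fosb, a subunit of the AP-1 transcription factor, had 4.86 ± 0.516 against 2.27 ± 0.531 FPKM (log2 fold change -0.85), and Egr2, a zinc finger transcription factor, 5.89 ± 0.685 against 2.11 ± 0.996 FPKM (log2 fold change -1.19). Bdnf, a neurotrophin gene, had 6.03 ± 0.260 against 4.50 ± 0.380 FPKM (log2 fold change -0.36), and Ier2 had 7.07 ± 0.566 against 4.21 ± 0.931 FPKM (log2 fold change -0.64). The list mean per library, in log2 units around the mean of all 6 libraries, was 0.447, 0.292 and 0.287 in the WT-labelled libraries and -0.383, -0.026 and -0.616 in the APP/PS1-labelled libraries, with the library labelled APP/PS1 replicate 2 nearest to the other label (exact two-sided permutation p = 0.1, the smallest the design allows). The mitochondrial share of FPKM was 9.3%, 8.9% and 9.3% in the WT-labelled and 10.3%, 9.7% and 11.3% in the APP/PS1-labelled libraries. By this share too the library labelled APP/PS1 replicate 2 lay nearest to the other label and APP/PS1 replicate 3 farthest. By fry the adjusted p of the list was 0.214, and over the 10 alternatives it ranged from 1.22e-31 to 0.541. In the 4 libraries the median was -0.95 and 20 genes passed over the list alone.

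**Figure D2:**
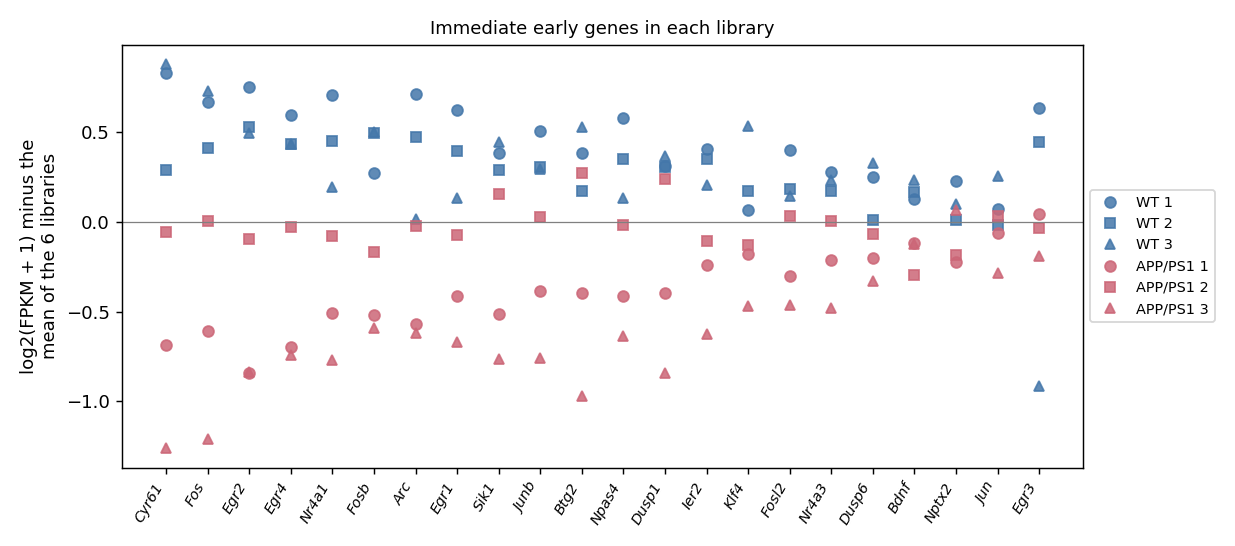
Each of the 22 immediate early genes in each library, as log2(FPKM + 1) minus the mean of the 6 libraries, with blue symbols for libraries labelled WT and red for libraries labelled APP/PS1. The red symbols lie mostly under the blue ones, and the red squares, the library labelled APP/PS1 replicate 2, lie nearest to them.

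Other neuronal and stress groups were lower by the preset-correlation test, and 1 library of each label again went against it by App and Prnp. Of the 18 unfolded protein response and heat shock genes, 15 were negative, with a median of -0.14 (camera adjusted p = 0.000542, and adjusted p = 0.541 with an estimated correlation). Hsph1, a heat shock protein of the Hsp110 family, fell from 41.4 ± 2.30 to 34.0 ± 1.40 FPKM and Pdia6, a protein disulfide isomerase, from 21.7 ± 0.679 to 17.9 ± 1.38 FPKM, both when adjusted over the list alone, where 1 gene passed in the 4 libraries. Of 11 dentate granule neuron markers 11 were negative with a median of -0.19 (camera adjusted p = 0.000618, and adjusted p = 0.752 with an estimated correlation), among them Lct at 5.83 ± 0.285 against 4.12 ± 0.993 FPKM and Prox1, the granule cell transcription factor, at 16.6 ± 2.97 against 13.5 ± 0.755 FPKM, and 0 passed over the list alone, against 1 in the 4 libraries. Of 21 glutamatergic synapse genes 17 were negative with a median of -0.05 (camera adjusted p = 0.0132, and adjusted p = 0.558 with an estimated correlation). Homer1 fell from 20.6 ± 1.0 to 15.7 ± 0.391 FPKM over the list alone, and Camk2a, the alpha subunit of the calcium/calmodulin kinase of synapses, had 261 ± 1.67 against 241 ± 13 FPKM. The list means per library of all 3 lists separated by label (exact two-sided permutation p = 0.1). Those of the complement list, which did not pass by camera (adjusted p = 0.161), separated in the same way. These exact p-values were not adjusted over the lists, and some lists could reach 0.1 by chance. Separation alone is thus weak evidence for a list. The means of the dentate granule list were 0.005, 0.034 and 0.321 against -0.028, -0.15 and -0.182, highest in WT replicate 3. Those of the unfolded protein response and heat shock list were 0.187, 0.064 and 0.113 against -0.176, 0.017 and -0.206. Those of the glutamatergic synapse list were 0.009, 0.049 and 0.045 against -0.039, -0.016 and -0.048. The heat shock and glutamatergic synapse means lay nearest to the other label in APP/PS1 replicate 2 and farthest in APP/PS1 replicate 3, as the mitochondrial share did. The values with an estimated correlation were the highest over the alternatives of each list, and the lowest were 2.61e-05, 1.62e-05 and 0.00768. The call for dentate granule neurons was lost without the library labelled WT replicate 3 (adjusted p = 0.0858) and in the 4 libraries (0.421). That for the glutamatergic synapse was lost without WT replicate 2 (0.0709), WT replicate 3 (0.0690) or APP/PS1 replicate 3 (0.0755) and in the 4 libraries (0.0680).

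Myelin and choroid plexus genes passed on the higher side in the APP/PS1-labelled libraries by camera with a preset correlation, at an adjusted p = 2.16e-06 for both, while their list means overlapped between the labels. With an estimated correlation the adjusted p = 0.756 for myelin and adjusted p = 0.752 for choroid plexus. Of 20 oligodendrocyte and myelin genes 18 were positive with a median of 0.17, and Opalin, an oligodendrocyte membrane glycoprotein, rose from 5.87 ± 0.0446 to 7.99 ± 0.572 FPKM, the 1 gene to pass over the list alone. Tspan2 had 15.1 ± 1.5 against 18.7 ± 1.13 FPKM and Mog, a myelin surface protein, 14.8 ± 1.0 against 17.6 ± 1.40 FPKM. Of 18 choroid plexus genes 16 were positive with a median of 0.21, and Sostdc1, a secreted antagonist of BMP signalling, rose from 19.0 ± 1.69 to 25.9 ± 2.39 FPKM over the list alone. Kcne2, a potassium channel subunit, had 5.61 ± 0.979 against 7.52 ± 0.503 FPKM. Leptomeningeal fibroblast genes passed on the lower side by the same test (adjusted p = 0.0266, and adjusted p = 0.779 with an estimated correlation), 9 of 11 negative with a median of -0.31, and Bmp6 had 5.66 ± 0.0969 against 4.38 ± 0.739 FPKM, with 0 past the threshold over the list alone (1 with an unadjusted p under 0.05). The myelin list mean per library was -0.06, -0.211 and 0.023 in the WT-labelled and 0.092, -0.034 and 0.19 in the APP/PS1-labelled libraries (exact two-sided permutation p = 0.2). It was lowest in WT replicate 2 and highest in APP/PS1 replicate 3, as was the mitochondrial share (8.9% and 11.3%). For choroid plexus it was -0.127, 0.084 and -0.27 against 0.114, 0.178 and 0.021 (exact p = 0.2). For fibroblasts it was 0.059, 0.078 and 0.202 against -0.077, 0.191 and -0.453 (exact p = 0.3), lowest in the library labelled APP/PS1 replicate 3. For myelin, choroid plexus and fibroblasts the adjusted p with an estimated correlation was the highest over their alternatives, and the lowest were 7.28e-10, 8.46e-15 and 1.94e-05. Choroid plexus was no longer past the threshold without the library labelled WT replicate 3 (adjusted p = 0.0520) or in the 4 libraries (0.263), where 0 of its genes, Sostdc1 included, passed over the list alone. In the 4 libraries the list median was 0.087, against 0.21 with all libraries. Sostdc1 itself had a log2 fold change of 0.52 there, against 0.43 with all libraries. The fibroblast call was lost without WT replicate 2 (adjusted p = 0.0545), WT replicate 3 (0.321) or APP/PS1 replicate 3 (0.627). In the 4 libraries, where App and Prnp followed the labels, 10 myelin genes passed over the list alone. The 2 libraries left out had the myelin means nearest to the other label, so a larger count could be foreseen. Where App and Prnp were low, in WT replicates 1 and 2 and APP/PS1 replicate 2, the myelin means were -0.06, -0.211 and -0.034. Where both were high they were 0.023, 0.092 and 0.19, without overlap. Lysosome, thalamus and CA2 and CA3 means also separated by this level, and other lists did not. This grouping was made after the values were seen and not tested.

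**Figure D3:**
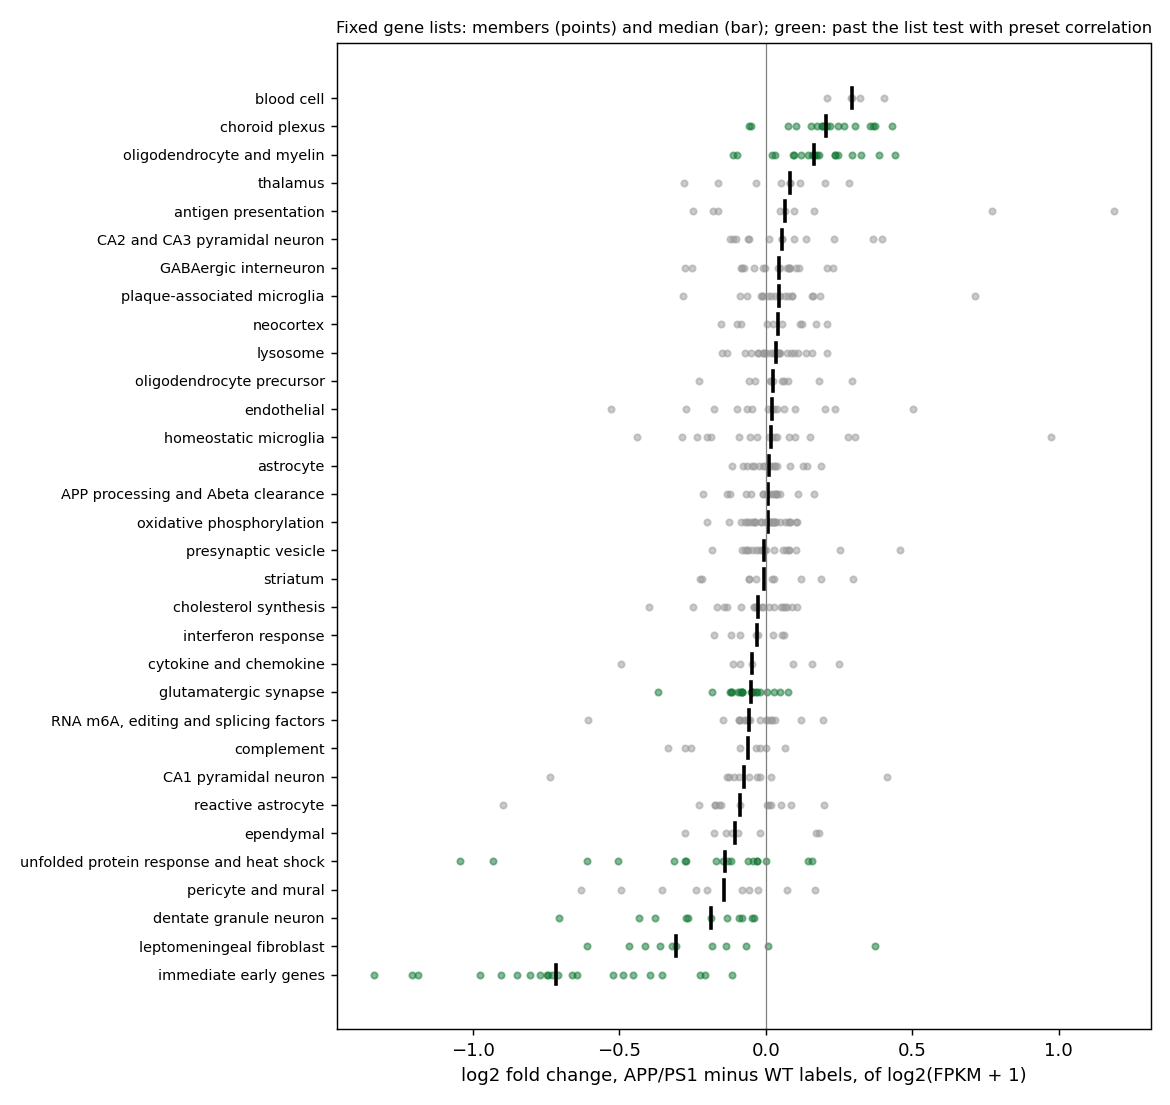
Log2 fold change of log2(FPKM + 1), APP/PS1-labelled minus WT-labelled libraries, for each member of 32 gene lists (points) with the list median (black bar). Green lists passed camera with a preset correlation, of which immediate early genes had the lowest median, -0.72.

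Glial and immune lists tied to amyloid pathology did not pass by camera between these labels, which App and Prnp contradicted in 2 libraries. Of 19 plaque-associated microglia genes 13 were positive with a median of 0.04 (adjusted p = 0.161), and 0 passed over the list alone by limma (2 with an unadjusted p under 0.05). Lgals3bp, a secreted glycoprotein, had 3.04 ± 0.212 against 5.82 ± 2.08 FPKM and Tyrobp, the TREM2 adaptor, 7.94 ± 1.41 against 9.10 ± 0.565 FPKM. Cst7, a cystatin seen in plaque microglia, lay under the filter and was listed at 0, 0 and 0.395 FPKM in the WT-labelled libraries and at 0.694, 0 and 1.17 FPKM in the APP/PS1-labelled libraries. The 18 homeostatic microglia genes had a median of 0.02 (adjusted p = 0.819), with Fcrls at 2.04 ± 1.17 against 4.73 ± 0.884 FPKM and Aif1 at 2.24 ± 0.179 against 1.66 ± 0.125 FPKM. Among 8 complement genes (adjusted p = 0.161) 2 fell over the list alone: C1qb from 16.7 ± 2.0 to 13 ± 0.538 FPKM and C1qc from 10.2 ± 0.754 to 8.34 ± 0.540 FPKM, subunits of the same initiating complex as C1qa, which had 21.8 ± 1.12 against 22.9 ± 0.549 FPKM. Neither C1qb nor C1qc passed over the list alone in the 4 libraries, where the count for complement was 0. Their log2 fold changes there were -0.36 and -0.23, against -0.33 and -0.26 with all libraries. The complement list means per library were 0.041, 0.004 and 0.132 in the WT-labelled and -0.019, -0.049 and -0.108 in the APP/PS1-labelled libraries. They separated by label (exact two-sided permutation p = 0.1), although camera made no call. Reactive astrocyte genes (adjusted p = 0.400), with Hspb1 at 12.6 ± 2.03 against 6.68 ± 3.22 FPKM, and other astrocyte genes (adjusted p = 0.811) did not pass. Nor did the lysosome (adjusted p = 0.205), interferon response (0.570), antigen presentation (0.449) or cytokine and chemokine (0.883) lists. By App and Prnp level, the lysosome means did not overlap. They were -0.018, -0.025 and -0.017 in WT replicates 1 and 2 and APP/PS1 replicate 2, where both were low. In WT replicate 3 and APP/PS1 replicates 1 and 3 they were 0.002, 0.035 and 0.023. The plaque-associated microglia means overlapped, -0.029, -0.087 and 0.022 against 0.02, 0.082 and -0.008. Differences by this level, seen after the fact, were not tested. H2-D1, whose reads are hard to separate from related class I genes, had 2.40 ± 2.22 against 5.95 ± 1.72 FPKM. The 18 genes of APP processing and Abeta clearance had a median of 0.01 (adjusted p = 0.960), with Ide, an Abeta-degrading protease, at 8.87 ± 0.360 against 10.1 ± 0.467 FPKM.

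The remaining neuronal, vascular and metabolic lists also did not pass. Among CA1 pyramidal neuron genes (adjusted p = 0.161) Nr3c2, the mineralocorticoid receptor, fell from 23.5 ± 4.22 to 13.6 ± 1.45 FPKM over the list alone, and among CA2 and CA3 genes (adjusted p = 0.335) Iyd rose from 1.28 ± 0.190 to 1.99 ± 0.130 FPKM over the list alone. Both calls ended in the 4 libraries, where 0 genes of either list passed over the list alone. The log2 fold changes there were -0.79 for Nr3c2 and 0.48 for Iyd, against -0.74 and 0.40 with all libraries. GABAergic interneuron (adjusted p = 0.492), presynaptic vesicle (0.811), neocortex (0.723), striatum (0.811) and thalamus (0.998) genes gave no call by camera. Thalamus genes had a positive median of 0.08, although camera placed them on the lower side. Endothelial (adjusted p = 0.821), pericyte and mural (0.161), ependymal (0.251), oligodendrocyte precursor (0.424) and blood cell (0.123) lists were not past the threshold, and the pericyte and mural list passed in the 4 libraries (adjusted p = 0.0110, and adjusted p = 0.673 with an estimated correlation), with 2 genes past the threshold over the list alone. Haemoglobin genes varied between libraries, Hba-a1 at 115 ± 37.1 against 151 ± 42.3 FPKM, and Hba-a1 and Hba-a2 are near-identical copies. Oxidative phosphorylation (adjusted p = 0.951) and cholesterol synthesis (0.625) did not pass. The reactive astrocyte, cytokine and chemokine, endothelial and cholesterol synthesis lists each had 0 genes past the threshold over the list alone and 1, a lower one, in the 4 libraries. In the list of m6A and splicing factors linked to circular RNA (adjusted p = 0.161), Adarb1 fell over the list alone (adjusted p = 0.000413), and Qk, a splicing factor that promotes circle formation, had 45.0 ± 5.32 against 51.5 ± 3.31 FPKM. These directions follow labels that App and Prnp contradicted in 1 library each.

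Circular RNAs, made when a splice donor joins an upstream acceptor, were compared to ask whether circles differ between the labels. A circRNA within Nme7 on chromosome 1 from 164312852 to 164403077, on the plus strand, rose from 4 reads in each WT-labelled library to 40, 40 and 10 reads in the APP/PS1-labelled libraries (log2 fold change 2.71, edgeR adjusted p = 0.0152, higher in 3 of 3 libraries). Pooled over libraries and scaled to total circRNA reads it was 6.66-fold higher. The files listed 3 other circRNAs in Nme7, described here after their values were seen. That from 164312855 to 164347879 had 0.333 ± 0.577 against 6.0 ± 2.0 reads, that from 164312852 to 164347879 had 1.00 ± 1.00 against 7.33 ± 4.16 reads, and that from 164312855 to 164403077 had 4.67 ± 4.04 against 14.3 ± 3.21 reads. Summed, the 4 Nme7 circles took 0.114% (exact 95% interval 0.065 to 0.186), 0.045% (0.019 to 0.088) and 0.032% (0.012 to 0.069) of circRNA reads in the WT-labelled libraries. They took 0.368% (0.288 to 0.463), 0.388% (0.302 to 0.489) and 0.159% (0.108 to 0.226) in the APP/PS1-labelled libraries (exact permutation p = 0.1). The Nme7 gene stood at 2.84, 2.74 and 3.41 FPKM against 9.39, 9.23 and 6.53 FPKM.

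By edgeR 1 circRNA was higher and 0 lower, with 65 higher and 48 lower at an unadjusted p under 0.05, where 106.6 were expected in all. DESeq2 also gave 1 higher (adjusted p = 0.0279 for the Nme7 circle) and 0 lower, with 48 and 33 at an unadjusted p under 0.05. In the Snhg14 locus, a host of clustered small nucleolar RNAs, a circRNA on chromosome 7 from 59451255 to 59451378 on the minus strand had 0 reads in every WT-labelled library and 4, 3 and 10 reads in the APP/PS1-labelled libraries. That is at least 5.03-fold higher against a floor of 3 reads over the group, and it did not pass (adjusted p = 0.662). A circRNA of Ppp1r21 on chromosome 17 from 88565640 to 88583981 had 12.3 ± 8.74 against 2.33 ± 4.04 reads and did not pass (adjusted p = 0.662). Among 12 tested circRNAs from hosts listed beforehand as brain-abundant or disease-linked, 1 had an unadjusted p under 0.05: a circRNA of Rims2, a presynaptic active zone gene, on chromosome 15 from 39274975 to 39345620, with 0.333 ± 0.577 against 3.33 ± 0.577 reads (adjusted p = 0.831). A pair of circRNAs known by number alone, mmu_circ_0005762 with 0.333 ± 0.577 against 7.67 ± 5.51 reads and mmu_circ_0005207 with 7.67 ± 2.08 against 0.667 ± 1.15 reads, did not pass either. At this depth simulated 2-fold changes were recovered in 2% and 4-fold changes in 28% of cases, so most differences of such a size were not detectable. The Nme7 circle lost its call without the libraries labelled WT replicate 1 (adjusted p = 0.386), WT replicate 2 (0.0932), WT replicate 3 (0.223) or APP/PS1 replicate 2 (0.109) and in the 4 libraries whose App and Prnp followed their labels (0.603), with a range of 0.00112 to 0.603 over its alternatives, and without APP/PS1 replicate 2 the Ppp1r21 circle passed (0.00954), 1 circRNA lower. In the settings where its call was lost, the Nme7 circle had log2 fold changes of 2.82, 2.68, 2.63, 2.40 and 2.33, in the same order. With all libraries it had 2.71.

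**Figure D4:**
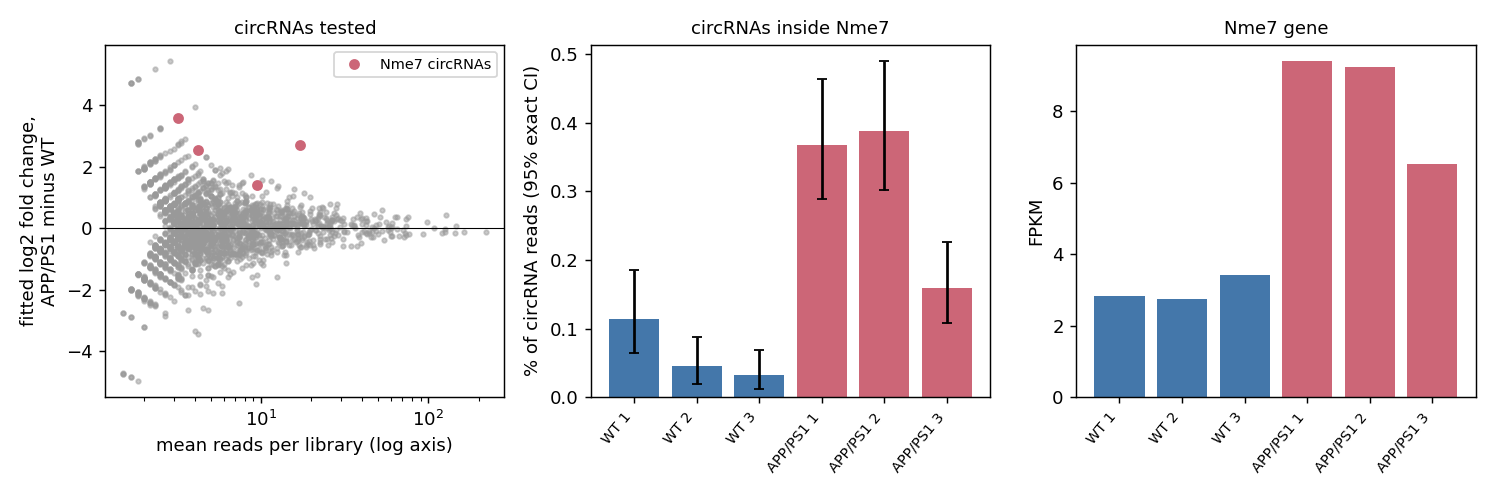
Left, fitted log2 fold change against mean reads per library (log axis) for 2132 circRNAs, with the 4 of Nme7 in red. Middle, share of circRNA reads from Nme7 per library with exact 95% intervals, and right, FPKM of the Nme7 gene per library, blue for libraries labelled WT and red for APP/PS1, where the gene reached 9.39 FPKM.

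Total circRNA abundance was compared next. Reads over all circRNAs came to 16902 ± 2567 in the WT-labelled and 19032 ± 841 in the APP/PS1-labelled libraries, a ratio of 1.13 (exact two-sided permutation p = 0.2). The sums carry the sequencing depth of each library, which is not given in the sources used here, so the ratio is not corrected for depth.

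The last comparison asked whether circRNA differences go with those of the host messenger RNA. Over 168 host genes with 213 circRNAs, averaged per host, the log2 fold changes correlated across genes with a Pearson r of 0.244 (permutation p = 0.00223, adjusted p = 0.00446) and a Spearman rho of 0.178 (p = 0.0208, adjusted p = 0.0208), 2 relations in the family. Genes are not independent replicates, and both fold changes came from the same 6 libraries. A positive rho, of at most 0.15, also arose in 8 other splits of these libraries into 3 against 3. The permutation p-values test against 0 and do not take that into account. Without the 2 hosts farthest from the median gene fold change the Pearson r was 0.153 (p = 0.0489), and without Nme7 0.189 (p = 0.0163). The Spearman rho did not pass with a stricter circRNA filter (rho 0.207 over 58 hosts, p = 0.119) or in the 4 libraries in which App and Prnp followed the labels (rho 0.112, p = 0.147). The Pearson r passed in both, at 0.449 (p = 0.00151) with the stricter filter and 0.194 (p = 0.0158) in the 4 libraries.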

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

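The 4-library fit was chosen after seeing the data. Other filters, the pseudocount, quantile or TMM scaling and limma without trend left every count of genes within 1.5 times, and the median log2 fold change over all genes was at most 0.0109 under either scaling. Genes higher numbered 1, and 2 with array weights, 11 in 4 libraries, 3 at an adjusted p under 0.1, 24 at an unadjusted p under 0.05 with a 1.5-fold change, and 1 to 8 with single libraries left out (4, 1 and 5 without WT replicates 1 to 3, 1, 8 and 2 without APP/PS1 replicates 1 to 3). Genes lower numbered 2, and 16 in 4 libraries, 4 at an adjusted p under 0.1, 46 at an unadjusted p under 0.05 with a 1.5-fold change, and 1 to 22 with single libraries left out (3, 1 and 6 without WT replicates 1 to 3, 5, 22 and 3 without APP/PS1 replicates 1 to 3). The replicate block gave 1 gene higher and 0 lower (limma, 461 lower at an unadjusted p under 0.05). Same-numbered libraries did not deviate together (correlations 0.01, -0.056 and -0.094), so no pairing by number was seen. With so few libraries a shared litter or day cannot be excluded in this way. With the block Cdc42se1 (limma, adjusted p = 0.0646) and Tspan5 (0.151) were the calls lost, and no circRNA or list call changed.

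circRNAs higher numbered 1, and 0 in 4 libraries (edgeR, 61 at an unadjusted p under 0.05), 64 at an unadjusted p under 0.05 with a 1.5-fold change, and 0 to 1 with single libraries left out (0 without each WT replicate and without APP/PS1 replicate 2). circRNAs lower numbered 0, and 48 at an unadjusted p under 0.05 with a 1.5-fold change, and 0 to 1 with single libraries left out (1 without APP/PS1 replicate 2). Gene lists past the threshold numbered 7, and 0 with an estimated correlation, 0 with fry and 3 to 9 with single libraries left out (3 without WT replicate 3, 9 without WT replicate 1 or APP/PS1 replicate 2). The rho of circRNA and host fold changes was 0.178, and 0.207 with the stricter filter and 0.112 in 4 libraries, neither past the threshold, while the Pearson r passed in both. The circRNA total ratio ran from 1.04 to 1.20. Log2 fold changes of genes not past the threshold turned sign, as ranges with single libraries left out, for Gjb6 (-0.23 to 0.009), Ifit3 (-0.324 to 0.092) and Hba-a2 (-0.094 to 0.567), each without APP/PS1 replicate 3, Pde10a (-0.372 to 0.039, without APP/PS1 replicate 1) and Bst2 (-0.02 to 0.108, without WT replicate 2), and for Gbp2 in 4 libraries (0.003). Over the single genes, lists and circRNAs, 2520 values kept direction and side of the threshold, 40 came to pass, 34 ceased to pass and 6 turned. Apart from settings with fewer libraries, the cause was not tested. Voom and DESeq2 on genes, a gene-table library size and a circRNA pseudocount were not run, as the units do not allow them. Depth limits circRNAs, with 26 reads over all libraries at the median circRNA.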

Other observations

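Chosen only after their result was seen were the tests of the mitochondrial list, the fit to 4 libraries, the splits for genes and for the circRNA and host rho, the count of libraries out of place, and the immediate early genes without both doubted libraries and by library mean. Genes encoded in the mitochondrial genome were higher in the APP/PS1-labelled libraries by camera with a preset correlation (p = 1.46e-09, and p = 0.105 with an estimated correlation). All 13 were positive, with a median log2 fold change of 0.20 (range 0.07 to 0.35), and 8 passed over the list alone. The list mean per library was -0.077, -0.156 and -0.061 in the libraries labelled WT replicates 1 to 3 and 0.081, -0.01 and 0.223 in those labelled APP/PS1 replicates 1 to 3 (exact permutation p = 0.1), and in the 4 libraries camera gave p = 5.75e-09 with a median of 0.24. Nuclear oxidative phosphorylation genes had a median of 0.01, and the difference between these lists was not tested. Mitochondrial transcripts made up 9.3%, 8.9% and 9.3% of FPKM in the WT-labelled and 10.3%, 9.7% and 11.3% in the APP/PS1-labelled libraries, whose labels App and Prnp contradicted in 1 library each.

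In the fit to 4 libraries H1fx, a linker histone gene, was higher in the APP/PS1-labelled libraries (limma, adjusted p = 0.000414). It was listed at 0, 0 and 16.9 FPKM in the WT-labelled and at 17.3, 0 and 17.6 FPKM in the APP/PS1-labelled libraries. Cds2, of phosphatidylinositol synthesis, stood at 13, 14.1 and 69.5 against 66.0, 13.8 and 67.2 FPKM. Arc, an immediate early gene of synapses, stood at 150, 126 and 91.9 against 60.8, 89.2 and 58.8 FPKM. These were picked after their values were seen. Over the 9 other splits of the 6 libraries the rho of circRNA and host fold changes was at most 0.15, against 0.178 by label. It was positive in 8 of them, so a rho above 0 also arose without the labels.

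App and Prnp were high in the library labelled WT replicate 3 and low in the library labelled APP/PS1 replicate 2. Scaling of the whole library is argued against by the median of all tested genes in the library labelled WT replicate 3, which differed from the other WT-labelled libraries by 0.017 in log2 units, where App differed by 1.06. Depth cannot be judged in this way, since FPKM are already scaled for it. An exchange of labels between the genotypes may account for the pattern: by both genes 2 libraries lay nearer to the other genotype, 1 of each. H1fx and Cds2, picked after their values were seen, split the libraries like App. Of the 25 genes called in the 4 libraries other than App and Prnp, H1fx and Cds2 included, in a count made after their values were seen, 5 placed both left-out libraries nearer to the other label on the log2(FPKM + 1) scale, 4 both nearer to their own and 16 set both on 1 side (3, 5 and 17 on the FPKM scale). This count cannot weigh for or against an exchange. Genes that differ for reasons other than genotype can place each left-out library on either side. An exchange stays a hypothesis, and a transgene carrier status that differs from the label for another reason was not tested.

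Tmem127, Cdc42se1 and Tspan5 each sat at 1 of 2 levels with little spread within a label. Per-gene estimates that switch between levels from library to library could give such calls: the split of the libraries labelled WT replicate 1, APP/PS1 replicate 1 and APP/PS1 replicate 2 against the rest held 6 genes with an all-or-none pattern, against 3 by label, and so did the split that App and Prnp follow, with 5 genes past the threshold, which may reflect genotype instead. With 10 splits a share under 0.05 cannot be reached, and 7 splits gave as many genes past the threshold, 3 by label and 15 at the highest, in the first split named, several times the count by label, which may point to a structure of the libraries outside the labels that was not tested further. For circRNAs 5 of 10 splits gave as many, 1 by label and 4 at the highest other, and for gene lists 3 of 10, 7 by label and 8 at the highest other. In WT replicate 3, where App was high, Tmem127, Cdc42se1 and Tspan5 stood at 2.93, 14.7 and 17.1 FPKM, near the other WT-labelled libraries. In APP/PS1 replicate 2, where App was low, they stood at 21.9, 6.32 and 6.50 FPKM. For these genes the values argue against an effect of transgene level, as read from App and Prnp. A difference by the labelled genotype or by strain stays open and untested for them.

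Immediate early genes were lower in the APP/PS1-labelled libraries by camera with a preset correlation, a call lost with an estimated correlation (adjusted p = 0.541) and not made by fry (0.214), and by limma 0 of 22 passed over all genes tested (18 with an unadjusted p under 0.05). Fewer dentate granule neurons in the tissue are argued against as the whole cause by the median of their markers, -0.187, above the -0.72 of the immediate early genes. A permutation of genes between the lists gave a one-sided p = 3.0e-04. It takes genes as independent and does not measure the spread between libraries. The estimated correlation between genes was 0.453 in the immediate early and 0.317 in the dentate granule list. The lower median did not rest on the 2 doubted libraries, since without both it was -0.952. Their list means, 0.287 and -0.026, lay nearest to the other label. A larger difference without them could thus be foreseen and bears on no cause. Animals handled or killed on different occasions could give the same pattern and cannot be told apart from the labelled genotype, as no label gives a day and the list mean separated the libraries by label with the smallest exact permutation p the design allows, 0.1. Grouped by App and Prnp level instead, the list means overlapped. They were 0.447, 0.292 and -0.026 in WT replicates 1 and 2 and APP/PS1 replicate 2, where both genes were low. In WT replicate 3 and APP/PS1 replicates 1 and 3, where both were high, they were 0.287, -0.383 and -0.616. The list thus did not separate by transgene level. An effect of the labelled genotype stays open as a hypothesis, as does a difference in RNA or tissue quality, which was not tested, since the mitochondrial share of FPKM (9.3%, 8.9% and 9.3% against 10.3%, 9.7% and 11.3%) also separated the labels, with the library labelled APP/PS1 replicate 2 nearest to the WT-labelled ones.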
